A study of Mus musculus with 3 samples.

How the data were processed

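The data were RNA sequencing libraries from polysomes captured with anti-EGFP antibodies in the cortex-amygdala transition zone of mice of the Lypd1-EGFP-L10a line OI82, with 3 libraries from 3 mice. Whether any library pooled animals was not stated in the sources used here. The deposited files give whole-number counts of reads per gene, 1 file per library, not normalized. Reads were aligned with STAR 2.0.0e to mm10 and counted with HTSeq, per the submitters' processing notes. The gene annotation, the strand setting and the library kit were not given in the sources used here. Antisense and overlapping genes can therefore not be told apart, and reads with more than 1 alignment were kept out of the gene counts, which lowers genes with near-identical copies such as ribosomal protein genes.

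Each file listed 32532 genes and 5 summary classes. The summary classes stayed out of library sizes and tests. Of all entries listed, reads that HTSeq placed in no counted feature made up 34.1 ± 10.1% (SD, n = 3). Entries aligned to more than 1 place made up 24.5 ± 8.13% and reads ambiguous between genes 1.54 ± 0.387%. Assigned counts were 18526251, 24690301 and 8668527 in replicates 1, 2 and 3. A count of 0 was read as at most 3 counts, which is 0.122 to 0.346 CPM. This floor covers counting error only, since the reads carry no stated molecular identifiers. Some genes carry only the name of an unnamed cDNA clone, and those took 0.966% to 1.52% of counts.

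Levels are CPM, the usual scaling of a gene's counts to the total assigned to genes in its library, without length correction. A gene was called detected at 1 CPM or more in each library. Log2 values use log2(CPM + 1), which understates differences of low genes. Folds given for contrasts come from the mean log2 difference and share this limit. The 31 gene lists (cell classes, transmitters, cortical, amygdalar and other regional markers, receptors, channels, peptides, Ly6 family, immediate-early and sex-linked genes), the tests and most alternatives were fixed before the data were examined. Of 443 list entries 440 were matched to the files by symbol, giving 416 distinct genes; 3 erythrocyte entries were not matched. The named genes were chosen by a rule, also fixed then. It takes the 3 members of each list with the highest mean CPM, up to 5 list members called as varying, Lypd1, Rpl10a, Slc17a7, Slc17a6, Gad1, Gad2 and Slc32a1, the 10 most abundant genes, and the 20 varying genes with the widest range among those with a mean of 5 CPM or more. Some genes that the rule names are not reported here. Genes named outside the rule were chosen after their values were seen, apart from the 6 further cholinergic markers of the last paragraph.

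Differences of list medians were taken within each library and tested over the 3 libraries with an exact two-sided sign-flip permutation test, with Benjamini-Hochberg adjustment over 14 contrasts. The smallest p this test can give is 0.25 with 3 libraries and 0.5 with 2. Percentiles of list medians come from 10000 random lists of the same size drawn from the 20785 genes with a count in any library. Variation between the libraries was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, an intercept-only model, trended dispersion and the upper tail of the chi-square goodness-of-fit test on 2 degrees of freedom. Benjamini-Hochberg adjustment covered the 15336 genes with a mean of 1 CPM or more, with a threshold of 0.05. List enrichment among called genes used a two-sided Fisher's exact test, over lists with at least 3 tested members. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and figures used matplotlib 3.10.9.

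The variation test was tested on simulated data, with counts for the 15336 genes drawn from the real means, library sizes and trended dispersion. Each of 5 draws held 200 planted genes. The test recovered 44.4% of genes raised 8-fold and 94.4% of genes raised 64-fold in 1 library. Of its calls 11.3% were false, and it called 0 genes with none planted. That share of false calls is above the 5% the threshold aims at. Genes lowered in 1 library were not simulated. The draws follow the dispersion that the test assumes, with no scatter of genes around it. Neither the share of false calls nor the 0 calls therefore carries over to the real data.

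Gene coordinates and exon lengths come from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Lengths were found for 73.4% of all listed genes, which is below the 80% set for this correction, but for 91.7% of genes with a mean of 1 CPM or more and for all 416 list genes, so the correction was run for these. The alternatives were other detection thresholds, TMM or DESeq2 1.42.0 scaling, other filters, a common dispersion, DESeq2's dispersion outliers, a pseudocount of 0.1, list means, length correction and leaving out each replicate. Library totals without the 3 most abundant genes and random lists matched on length were added after seeing the data. The design has 1 group, so no comparison between groups was made.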

Results

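The series profiled RNA captured with tagged ribosomes from the cortex-amygdala transition zone, a strip of tissue where ventral cortex meets the amygdala. The mice carried EGFP fused to ribosomal protein L10a under Lypd1 regulatory DNA, in the transgenic line OI82. Polysomes of the tagged cells were captured with antibodies to EGFP, a method known as translating ribosome affinity purification, and the captured RNA was sequenced. There was 1 group, with 3 immunopurified libraries from 3 adult, untreated control mice, called replicates 1, 2 and 3 here. Whether each library came from a single mouse was not stated in the sources used here, so the spread given is that between libraries. Levels are given in CPM, the counts of a gene scaled to the library's assigned total. The libraries held 18526251, 24690301 and 8668527 counts assigned to genes, so replicate 3 had the least depth. A gene with 0 counts could have been present at up to 0.162, 0.122 and 0.346 CPM in replicates 1, 2 and 3, the level of 3 counts, a floor that covers counting error only. No unpurified tissue RNA and no other group was analysed here, so the values are levels in the captured RNA and not enrichments over the tissue. Values are the mean ± SD over the 3 libraries (n = 3) unless a single library is named.

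The gene whose regulatory DNA marks the line, Lypd1, was abundant in the captured RNA. Lypd1, which encodes a membrane-anchored protein of the Ly6 family that binds nicotinic acetylcholine receptors, measured 368 ± 202 CPM, with 232 in replicate 1, 601 in replicate 2 and 272 in replicate 3. It lay at the 96.6th percentile of detected genes on average. Its level was 12.9 times the median of detected genes, a log2 difference of 3.68 ± 0.79 that was positive in 3 of 3 libraries. Rpl10a, the gene of the tagged ribosomal protein, measured 140 ± 39.7 CPM and was 2.21 times the median of the other 71 detected cytosolic ribosomal protein genes, a log2 difference of 1.15 ± 0.24, positive in 3 of 3 libraries. With length correction the Lypd1 difference was 3.004 ± 0.792 and the Rpl10a difference 0.73 ± 0.26. Both differences were larger than their spread between libraries, but the exact two-sided sign-flip permutation test over 3 libraries cannot give a p below 0.25, which is what it gave for each (adjusted p = 0.269 over 14 contrasts, Benjamini-Hochberg). Rpl10a ranked 6th among the ribosomal protein genes by CPM and 20th after correction for transcript length. The counts do not separate endogenous from transgene reads of Rpl10a, and reads that align equally well to a pseudogene were not counted for any ribosomal protein gene. In the GRCm38 assembly Lypd1 (ENSMUSG00000026344.9) spans positions 125867622 to 125913101 on the minus strand of chromosome 1, and Rpl10a (ENSMUSG00000037805.15) spans 28328471 to 28331033 on the plus strand of chromosome 17. Their annotated exons cover 7038 and 2431 bases.

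Within the Ly6 family list, 8 of 10 members were detected, meaning at 1 CPM or more in each library. Lypd1 had the highest mean, followed by Thy1, a surface glycoprotein of projection neurons, at 283 ± 13.2 CPM, and Lynx1, a modulator of nicotinic receptors, at 183 ± 29.6 CPM. That order of Lypd1 and Thy1 rests on replicate 2, since Thy1 was the higher in replicates 1 and 3 (278.6 against 232.1 and 272.8 against 272.4 CPM) and on average after length correction. The spread of Lypd1 between the libraries was wider than that of either, and the excess was in replicate 2.

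The most abundant transcripts were the ribosomal RNA precursor, long non-coding RNAs and messenger RNAs, of neurons and of general cell functions. Rn45s, the ribosomal RNA precursor, took 7.99 ± 1.26% of the assigned counts. Among non-coding RNAs, the nuclear transcript Malat1 took 3.45%, 1.44% and 8.25% in replicates 1, 2 and 3, the imprinted transcript Meg3 took 2.21%, 1.39% and 4.67%, and Snhg11, a neuronal small nucleolar RNA host gene, took 0.618 ± 0.371%. Malat1, Meg3 and Snhg11 were each lowest in replicate 2 and highest in replicate 3. Snap25, a protein of the synaptic vesicle fusion machinery, led the messenger RNAs with 9016 ± 3618 CPM. Reads assigned to Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, came next at 5637 ± 1463 CPM. The counts do not show whether all of these came from its messenger RNA. Srrm2, a splicing factor, measured 5607 ± 1125 CPM. The cytoskeletal gene Map1b measured 4405 ± 568 CPM and the 14-3-3 family gene Ywhaz 3119 ± 1575 CPM. Together the 10 most abundant genes of each library took 16.3% to 23.4% of its counts.

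Neuronal markers stood far above the markers of every other cell class on the lists. All 14 pan-neuronal markers were detected, with a list median of 434 ± 111 CPM, led by Snap25, by the dendritic microtubule protein Map2 at 1059.8 ± 45.6 CPM and by the synaptic vesicle protein Syn1 at 954 ± 290 CPM. The neuronal median exceeded the astrocyte median 5.72-fold (log2 difference 2.52 ± 0.79) and the oligodendrocyte precursor median 23.0-fold (4.52 ± 0.35). It exceeded the oligodendrocyte median 34.9-fold (5.13 ± 0.92) and the median of mural cells and fibroblasts 49.7-fold (5.63 ± 0.46). It exceeded the endothelial median 72.3-fold (6.18 ± 0.31) and the microglial median 163-fold (7.35 ± 0.90). The folds come from the log2(CPM + 1) differences, so for low lists such as the microglial one they understate the ratio of median CPM. These 6 differences were positive in 3 of 3 libraries and larger than their spread. Each had an exact sign-flip permutation p of 0.25, the smallest that 3 libraries allow, and an adjusted p of 0.269. With length correction the log2 difference was 4.27 for oligodendrocytes and 6.25 for microglia, and for microglia it was 6.32 with members of at least 1 CPM and 8.01 with a pseudocount of 0.1.

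**Figure D1:**
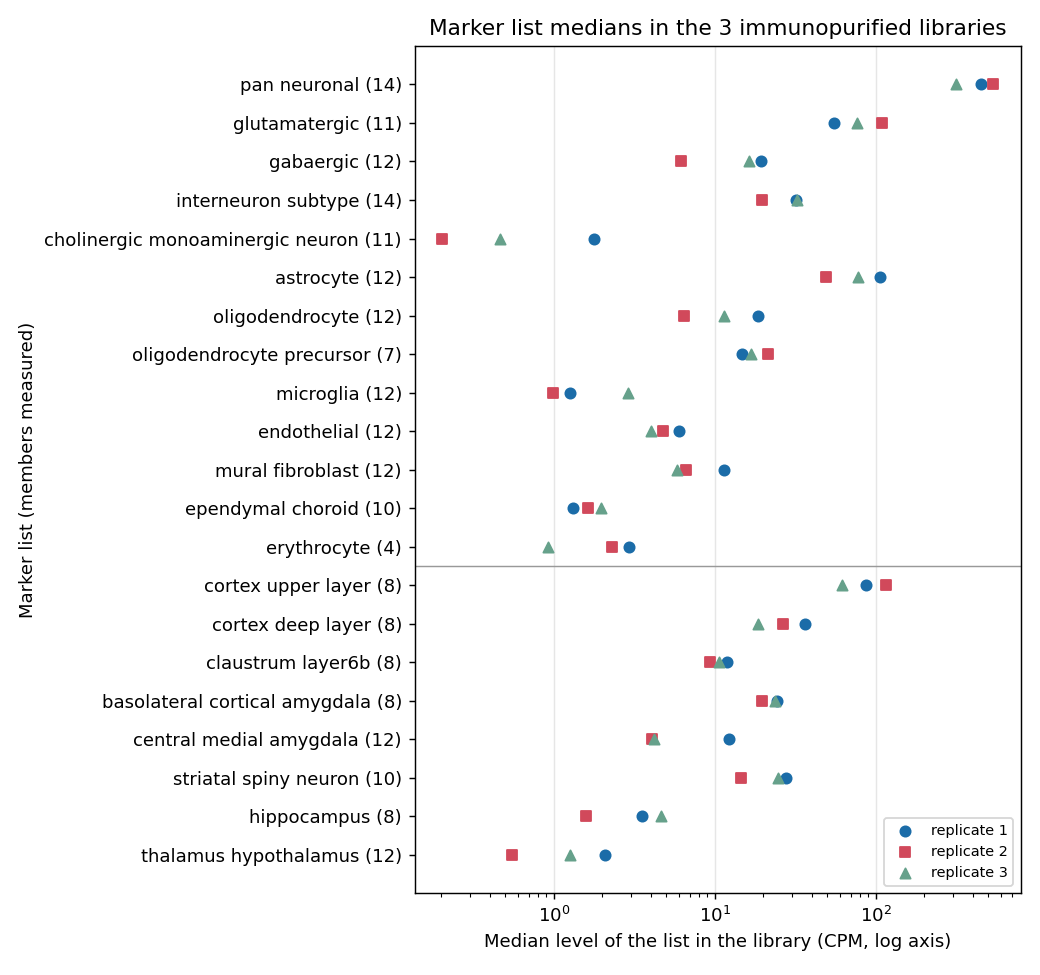
Median level of each marker list in CPM on a log axis, with 1 point for each of the 3 libraries and the number of measured members in brackets; cell classes are above the line and regional lists below it. The pan-neuronal medians lie between 315 and 535 CPM, while the microglial medians lie between 0.992 and 2.88 CPM.

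Glial and vascular transcripts were nevertheless present. All 12 astrocyte markers were detected, with a list median of 77.5 ± 28.3 CPM, and Slc1a2, the main astrocytic glutamate transporter, reached 845 ± 94.9 CPM. Aldoc, a glycolytic enzyme of astrocytes, measured 244 ± 123 CPM and the intermediate filament gene Gfap 444, 124 and 136 CPM in replicates 1, 2 and 3. Of the oligodendrocyte markers 11 of 12 were detected, and the myelin genes Mbp and Cnp measured 109 ± 32.8 and 44.9 ± 22.3 CPM. All 7 markers of oligodendrocyte precursors were detected, led by the proteoglycan Vcan at 105 ± 45.7 CPM, with Cspg4 at 24.9 ± 14.7 and Olig2 at 19.7 ± 10.4 CPM. Microglial markers were detected for 5 of 12 genes, and for up to 8 with 1 library left out, among them Aif1 and Csf1r at 7.41 ± 2.93 and 7.26 ± 3.01 CPM. Cx3cr1, the microglial gene with the highest mean, was not detected in all libraries, with 19.8, 0.486 and 2.88 CPM in replicates 1, 2 and 3. Endothelial markers were detected for 9 of 12 genes, led by the glucose transporter Slc2a1 at 33.1 ± 8.80 CPM, Slco1a4 at 10.6 ± 6.24 CPM and Flt1 at 5.61, 19.6 and 4.38 CPM in replicates 1, 2 and 3. Mural cell and fibroblast markers were detected for 8 of 12 genes, led by Myh11 (47.2, 7.21 and 6.69 CPM in replicates 1, 2 and 3), Rgs5 (18.1 ± 12.01 CPM) and Col1a2 (31.3, 6.56 and 10.7 CPM). Of the ependymal and choroid plexus markers 5 of 10 were detected, with Prlr at 24.1 ± 11.9 CPM and Kl at 30.5, 4.13 and 11.997 CPM in replicates 1, 2 and 3. Of the 4 measured erythrocyte genes 2 were detected, Alas2 at 9.32 ± 3.71 and Hbb-bs at 2.34 ± 1.13 CPM, while Hba-a2 measured 1.77 ± 1.002 CPM and fell short of 1 CPM in replicate 3.

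The captured RNA carried transcripts of both glutamatergic and GABAergic neurons. All 11 glutamatergic markers were detected, with a list median of 80.7 ± 27.6 CPM, led by the kinase Camk2a at 2756 ± 806 CPM, the vesicle protein Sv2b at 237 ± 20.8 CPM and the vesicular glutamate transporter Slc17a7 at 224 ± 45.5 CPM. Of the GABAergic markers 11 of 12 were detected, with a list median of 13.9 ± 6.91 CPM, led by the GABA-synthesizing enzyme Gad2 at 356 ± 108 CPM. The glutamatergic median was 5.81 times the GABAergic median, a log2 difference of 2.54 ± 1.28 that was positive in 3 of 3 libraries (exact sign-flip permutation p = 0.25, adjusted p = 0.269), with 1.47 in replicate 1, 3.96 in replicate 2 and 2.18 in replicate 3. Without replicate 2 it was 1.83 ± 0.51. Slc17a7 exceeded Slc17a6, the other vesicular glutamate transporter on the list (90.3 ± 32.6 CPM), by 1.34 ± 0.80 on the log2 scale. It exceeded the GABA-synthesizing enzyme Gad1 (90.1 ± 32.2 CPM) by 1.36 ± 0.84. Both pairs had the same sign in 3 of 3 libraries, with an exact sign-flip permutation p of 0.25. Slc32a1, the vesicular GABA transporter, measured 23.8 ± 10.3 CPM.

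The contrast of the transmitter lists depended on which genes were set against each other. For 2 further pairs, chosen after their values were seen, the signs were opposite. Slc17a7 minus Slc32a1 was 3.23 ± 0.86 on the log2 scale, positive in 3 of 3 libraries, and 2.32 ± 0.87 with length correction. Slc17a7 minus Gad2 was −0.64 ± 0.71 on the log2 scale and negative in 3 of 3 libraries, and it was −0.52 ± 0.71 after correction for transcript length. The mean of this pair was smaller than its spread between the libraries.

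**Figure D2:**
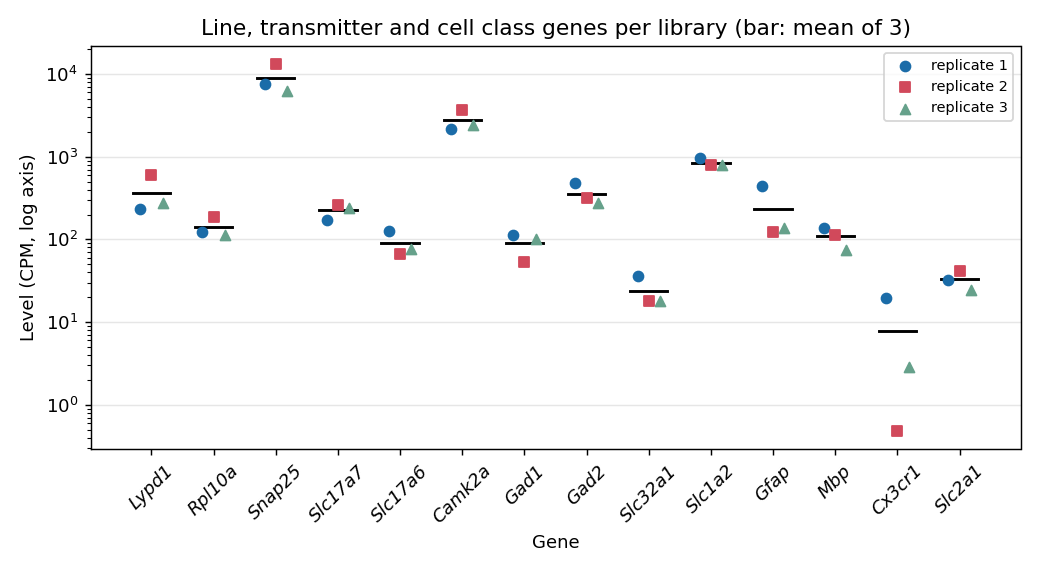
Level of 14 genes of the transgenic line, transmitter classes and cell classes in CPM on a log axis, with 1 point for each of the 3 libraries and a bar at their mean. Snap25 stands highest at 9016 CPM, Lypd1 lies at 368 CPM, and Cx3cr1 spans 0.486 to 19.8 CPM.

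Among interneuron markers 12 of 14 were detected, with a list median of 28.0 ± 7.10 CPM. The extracellular matrix protein Reln led at 175 ± 8.23 CPM, followed by the RNA-editing family gene Adarb2 at 72.4 ± 31.6 CPM and the cannabinoid receptor Cnr1 at 61.3 ± 14.3 CPM. Of the 11 cholinergic and monoaminergic markers 1 was detected in all libraries, the vesicular monoamine transporter Slc18a2 at 2.97, 6.80 and 19.4 CPM in replicates 1, 2 and 3, and with 1 library left out 1 to 4 were. Chat, the enzyme that makes acetylcholine, measured 28.6 CPM in replicate 1, 0.608 in replicate 2 and 1.61 in replicate 3, and the choline transporter Slc5a7 measured 15.9, 0.203 and 1.04 CPM.

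Markers of cortical layers and of the amygdala were both present, and upper-layer markers were more abundant than deep-layer ones. All 8 upper-layer markers were detected, with a list median of 88.3 ± 27.6 CPM and Rasgrf2, Cux1 and Unc5d at 237 ± 55.9, 165 ± 28.6 and 116 ± 22.0 CPM. Of the deep-layer markers 7 of 8 were detected, with a list median of 27.3 ± 8.98 CPM, led by the transcription factor Bcl11b at 144 ± 43.6 CPM, Crym at 70.9 ± 25.3 and Etv1 at 37.4 ± 17.7 CPM. Deep-layer minus upper-layer medians gave −1.68 ± 0.46 on the log2 scale, negative in 3 of 3 libraries, with an exact sign-flip permutation p of 0.25 and an adjusted p of 0.269.

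Markers of the basolateral and cortical amygdala exceeded those of the central and medial amygdala by 1.74 ± 1.04 on the log2 scale, positive in 3 of 3 libraries (exact sign-flip permutation p = 0.25, adjusted p = 0.269). Of the former list 7 of 8 genes were detected, and Lmo3, a transcriptional cofactor, measured 312, 751 and 239 CPM in replicates 1, 2 and 3, the vesicular zinc transporter Slc30a3 86.4 ± 19.9 CPM and Otof 67.3 ± 34.3 CPM. Of the latter list 6 of 12 genes were detected, with the estrogen receptor Esr1 at 42.1, 87.5 and 26.4 CPM in replicates 1, 2 and 3, Dlk1 at 75.5, 21.7 and 33.3 CPM and the transcription factor Lhx9 at 25.8 ± 4.59 CPM. With members under a mean of 1 CPM left out, the difference fell to 0.36 ± 0.60, smaller than its spread, and without replicate 1 it was 2.33 ± 0.19.

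Deep cortical and striatal markers were not separated. Their difference was 0.30 ± 0.55 on the log2 scale, positive in 2 of 3 libraries (exact sign-flip permutation p = 0.5, adjusted p = 0.5). It was −0.61 ± 0.85 after length correction, −0.0093 ± 0.785 with members of at least 1 CPM and 0.063 ± 0.513 without replicate 2. It was 0.50 ± 0.40 with list means and 0.60 ± 0.24 without replicate 3. Of the striatal list 7 of 10 genes were detected, with the phosphodiesterase Pde10a at 91.0 ± 15.4 CPM, the signalling regulator Rgs9 at 65.7 ± 33.5 CPM and the dopamine-regulated phosphatase inhibitor Ppp1r1b at 33.6, 92.9 and 34.1 CPM in replicates 1, 2 and 3.

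Claustrum and layer 6b markers were detected for 7 of 8 genes, with Nr4a2 at 16.6, 134 and 31.8 CPM in replicates 1, 2 and 3, Synpr at 60.5 ± 5.24 and Gnb4 at 27.2 ± 10.4 CPM. Hippocampal markers were detected for 4 of 8 genes, with a list median of 3.24 ± 1.54 CPM. The highest were Wfs1, Zbtb20 and Prox1 at 93.9 ± 31.99, 91.0 ± 31.5 and 39.2 ± 11.3 CPM. Markers of thalamus and hypothalamus were detected for 4 of 12 genes, with a list median of 1.30 ± 0.766 CPM. The highest were Rora at 141 ± 44.0 CPM and Tcf7l2 at 24.5 ± 11.6 CPM, while Prkch measured 0.486, 2.96 and 9.34 CPM in replicates 1, 2 and 3.

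Receptors and ion channels of fast signalling were broadly detected. All 22 glutamate receptor genes were detected, with a list median of 57.4 ± 14.3 CPM, and the AMPA receptor subunits Gria2, Gria3 and Gria1 measured 1156 ± 443, 573 ± 182 and 304 ± 20.6 CPM. Of the GABA receptor genes 14 of 15 were detected, with a list median of 60.7 ± 4.21 CPM and with Gabbr1 and Gabrb2 at 418 ± 94.7 and 217 ± 55.7 CPM. Of the voltage-gated channel genes 26 of 27 were detected, with a list median of 126 ± 44.0 CPM, led by the calcium channel Cacna1e at 656 ± 199 CPM and the sodium channels Scn8a and Scn2a1 at 619 ± 101.5 and 375 ± 47.8 CPM. Receptors for monoamines, acetylcholine, histamine, cannabinoids and adenosine were detected for 29 of 40 genes, led by the muscarinic receptor Chrm1 at 98.4 ± 20.1 CPM, then by Cnr1 and, at 53.0 ± 1.84 CPM, the nicotinic subunit Chrna4. Peptide and hormone receptors were detected for 27 of 41 genes, with Igf1r at 148 ± 14.9, the PACAP receptor Adcyap1r1 at 118 ± 37.8 and the neurotensin receptor Ntsr2 at 83.6 ± 38.0 CPM.

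Of the 34 neuropeptide and secretory genes 21 were detected. The granins Chgb and Scg2 measured 357 ± 137 and 182 ± 53.9 CPM, and Cck, which encodes cholecystokinin, measured 149 ± 15.9 CPM. The list median of 3.56 ± 0.34 CPM lay at the 18.5th percentile of 10000 random lists of the same size, and at the 87.1st percentile of random lists matched on transcript length, an alternative chosen after seeing the data. The median exon length of its members was 1381 bases, and CPM per kb was lower for genes with short exon lengths. For protein-coding genes with counts and 1 to 2 kb of exons the median was 1.4995, 1.72 and 2.27 CPM per kb in replicates 1, 2 and 3, against 2.42, 2.25 and 2.96 for 2 to 4 kb and 4.98, 4.43 and 5.17 for 8 kb or more.

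Steroid and nuclear receptors were detected for 12 of 13 genes, with a list median of 42.7 ± 21.1 CPM and the thyroid hormone receptors Thra and Thrb at 249 ± 37.7 and 128 ± 40.9 CPM. The orphan receptor Rorb measured 111 ± 41.7 CPM. Immediate-early genes, which neurons transcribe upon activity, were detected for 15 of 16 genes, with Egr1, Egr3 and Fosl2 at 412 ± 49.6, 178 ± 38.5 and 55.7 ± 11.2 CPM. All 5 sex-linked genes were detected. The Y-linked Kdm5d measured 55.4 ± 4.25 CPM and Eif2s3y 12.9, 26.3 and 59.99 CPM in replicates 1, 2 and 3, and Xist, the non-coding RNA that silences an X chromosome, measured 47.8, 1.26 and 78.4 CPM in replicates 1, 2 and 3. Over all lists, 322 of 416 distinct genes were detected, and 10 had 0 counts in all 3 libraries, among them the peptide genes Gal, Pmch and Ucn.

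The 3 libraries resembled one another at the level of whole profiles and differed gene by gene. Of the 32532 genes listed, 12773 were detected in all libraries, 11747 of them protein coding. Across 15336 genes with a mean of 1 CPM or more, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.889 for replicates 1 and 2, 0.887 for 1 and 3 and 0.903 for 2 and 3. Spearman's rho was 0.893, 0.896 and 0.908. Between 70.0% and 71.4% of genes lay within 2-fold in any pair of libraries. The counts of each pair differed far beyond sampling noise (chi-square per degree of freedom of 91.7 to 175), so no library was a copy of another. The biological coefficient of variation over all tested genes was 0.643, with a trended median of 1.07 for genes of 1 to 5 CPM and 0.323 for genes of 100 to 1000 CPM.

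Genes that varied between the libraries more than genes of their abundance numbered 32 of 15336, by edgeR's goodness-of-fit test with Benjamini-Hochberg adjustment, and 1200 genes had an unadjusted p under 0.05. Of the 32, 23 were highest in replicate 1, 6 in replicate 3 and 3 in replicate 2, while 22 were lowest in replicate 2 alone and 3 were tied at 0 counts in replicates 2 and 3. Xist varied most by p (adjusted p = 0.0002, edgeR), with its lowest value in replicate 2. Echdc2, a mitochondrial enzyme family gene, measured 68.0 CPM in replicate 1, 0.972 in replicate 2 and 11.1 in replicate 3. Wdfy2, an endosomal protein gene, measured 63.4, 1.46 and 8.42 CPM, and Kcnk10, a potassium channel gene, 49.7, 1.58 and 5.65 CPM. Lhx8, a transcription factor of cholinergic forebrain neurons, measured 34.9, 2.96 and 0.346 CPM, and Chat had the values given above (adjusted p = 0.0346, edgeR).

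Some of the other varying genes had no counts in a library. Capg, an actin-capping protein gene, stood at 17.3 CPM in replicate 1 with 0 counts in replicates 2 and 3, at least 142-fold above the level of 3 counts in replicate 2. The death receptor Fas and Methig1 stood at 21.7 and 26.0 CPM in replicate 1 with 0 counts in replicate 2, as did C130060K24Rik at 22.1 CPM and the unnamed transcript AK172662 at 22.2 CPM. Rnf151 measured 27.4, 0.0405 and 0.808 CPM, Oasl2, an interferon-induced gene, 27.5, 0.324 and 4.27 CPM, and the cytokine gene Flt3l 28.3, 0.364 and 15.1 CPM. Trmt61a, a transfer RNA methyltransferase, was lowest in replicate 1, with 0.216, 41.6 and 20.3 CPM, and the transcription factor Erg was highest in replicate 2, with 0.054, 20.4 and 1.15 CPM. Ttr, the thyroid hormone carrier made by choroid plexus, was highest in replicate 3, with 1.35, 3.97 and 54.6 CPM. The unnamed transcripts AK149000, AK051804 and AK154275 were also highest in replicate 3, at 35.9, 18.8 and 30.1 CPM. Nr4a2, a nuclear receptor of claustrum and layer 6b, was highest in replicate 2, with 16.6, 134 and 31.8 CPM (adjusted p = 0.0346, edgeR).

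These calls depended on which libraries were used. Leaving out replicate 1, 2 or 3 left 8, 5 or 22 called genes, of which 5, 4 and 20 were among the 32; no gene of the 32 was called in all 3 reduced sets, and Xist, Capg and AK149000 were called in 2.

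**Figure D3:**
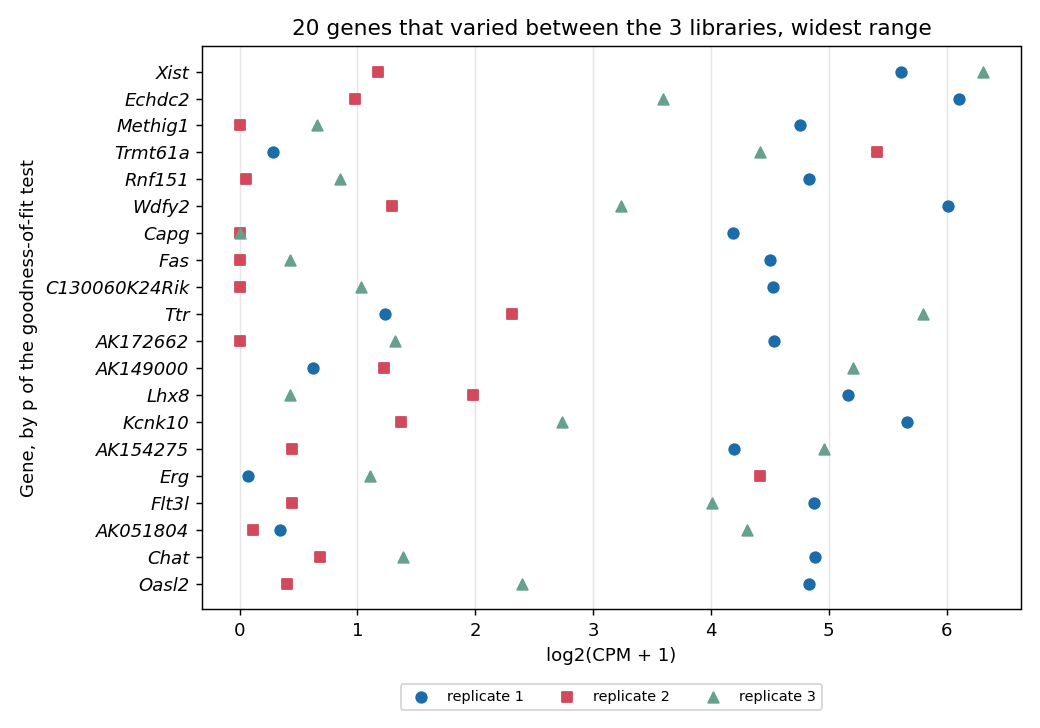
Log2(CPM + 1) of the 20 genes with the widest range among those that varied between the libraries and had a mean of at least 5 CPM, ordered by p, with 1 point for each of the 3 libraries. Xist is at 1.26 CPM in replicate 2 against 47.8 and 78.4 CPM in the others.

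None of the 31 lists passed the test for over-representation among the varying genes. With 32 called genes that test had little power, so this does not show that no list was over-represented. By Fisher's exact test on edgeR's calls, 0 lists passed at an adjusted p of 0.05 and 4 had an unadjusted p under 0.05. The lowest adjusted p was 0.113, shared by 4 lists with 1 called gene each. These were Chat of the cholinergic and monoaminergic list, Nr4a2 of the claustrum and layer 6b list, Ttr of the ependymal and choroid list and Xist of the sex-linked list. Over all genes tested, 4 of the 416 list genes were called. Adjusted within each list separately, with no adjustment across the 31 lists, 13 were. The 9 further genes were the choline transporter Slc5a7, the dopamine receptor Drd2, the astrocyte genes Gfap and S100b, the microglial Cx3cr1, the smooth muscle genes Acta2 and Myh11, the melanocortin receptor Mc3r and the GABA receptor subunit Gabrg3.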

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

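Reads that HTSeq placed in no counted feature are not used in any comparison of the report, and there were no control libraries to set them against. The type of feature counted was not given, so reads in introns cannot be told from reads outside genes. They made up 31.4% of the entries listed for replicate 1 (95% Wilson interval 31.40% to 31.42%), 25.6% for replicate 2 (25.62% to 25.64%) and 45.3% for replicate 3 (45.32% to 45.36%). The rule flags any such signal above 0, which says nothing about its size. The intervals cover counting error only, and the total includes entries aligned to more than 1 place, which can list a read repeatedly. Per assigned count there were 0.911, 0.533 and 1.23 such reads in replicates 1, 2 and 3. No explanation for the difference between the libraries was tested.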

How the results depend on the processing

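The alternatives of library totals without the 3 most abundant genes and random lists matched on length were chosen after seeing the data. All 14 contrasts but 1 kept their sign under length correction, the pseudocount of 0.1, list means, the filter on members and each left-out replicate, where these applied, and changes of size over 1.5-fold stand beside each contrast in the report; their p-values are at or above the 0.25 floor and say nothing about stability. The exception was deep cortical minus striatal markers, which reversed to −0.61 with length correction and to −0.0093 with members of at least 1 CPM; the cause was not tested. The number of varying genes was 32 with the trended dispersion, 779 with a common dispersion and 21 by DESeq2's dispersion outliers, 17 of them shared with the 32. A common dispersion of all genes is by construction too small for genes of 1 to 5 CPM, whose trended coefficient of variation was 1.07 against 0.643. Leaving out a replicate gave 5 to 22 varying genes, with 1 degree of freedom left: 8 without replicate 1, 5 without replicate 2 and 22 without replicate 3. Without a filter 24 genes were called, with a mean of 5 CPM or more 39 and with RLE scaling 33, of which 24, 29 and 32 were among the 32. The count of 0 enriched lists held under the 5 alternatives run. Detected genes ranged from 9924 at 5 CPM to 13626 at 0.5 CPM, and were 12990 without the 3 most abundant genes in the totals. At 5 CPM the detected members fell by over 1.5-fold in 11 of 31 lists, and at 0.5 CPM they rose by as much in 1. With random lists matched on length, 7 of 31 list percentiles crossed the middle. Of the named genes, 67 moved in percentile by more than their spread under length correction. Depth limits genes under 0.346 CPM in replicate 3.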

Other observations

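The genes of this paragraph are list members outside the naming rule, chosen after their values were seen. The progesterone receptor Pgr measured 57.1 ± 20.2 CPM (SD, n = 3, as for all values here) and the glucocorticoid and mineralocorticoid receptors Nr3c1 and Nr3c2 68.6 ± 9.55 and 50.4 ± 25.9 CPM, while the estrogen receptor Esr2 stayed at 1.02 ± 0.0764 CPM. The oxytocin receptor Oxtr measured 37.3 ± 4.65 CPM and the substance P receptor Tacr1 40.0 ± 1.61 CPM. The vasopressin receptor Avpr1a was at 1.46 ± 1.31 CPM, with 0 counts in replicate 2. The neuropeptide Y receptors Npy1r and Npy2r measured 31.7 ± 14.4 and 19.8 ± 7.71 CPM and the opioid receptor Oprm1 12.7 ± 1.504 CPM. Among peptide genes, Sst, which encodes somatostatin, reached 60.6 ± 15.5 CPM and the enkephalin gene Penk 38.4 ± 13.1 CPM, against 2.93 ± 0.754 CPM for Npy and 3.46 ± 2.42 CPM for Vip.

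The 9 list genes called by edgeR only when adjusted within each list separately, and not over all genes tested, were each highest in replicate 1. Acta2, smooth muscle actin, measured 22.6, 0.648 and 1.27 CPM in replicates 1, 2 and 3, and Myh11, smooth muscle myosin, 47.2, 7.21 and 6.69 CPM. Gfap measured 444, 124 and 136 CPM and the calcium-binding protein gene S100b 121, 36.1 and 24.8 CPM. Cx3cr1, the fractalkine receptor of microglia, measured 19.8, 0.486 and 2.88 CPM, and Drd2 47.1, 2.67 and 15.5 CPM. Over whole lists, 11 of 12 astrocyte, 9 of 12 oligodendrocyte, 9 of 12 GABAergic, 8 of 12 mural, 8 of 12 thalamic and hypothalamic and 3 of 4 erythrocyte genes were highest in replicate 1. The same held for 3 of 12 endothelial, 3 of 10 ependymal and choroid, 2 of 7 oligodendrocyte precursor and 2 of 12 microglial genes. Other lists leaned to another library. Highest in replicate 2 were 8 of 11 glutamatergic genes. Highest in replicate 3 were 8 of 12 microglial, 24 of 41 peptide and hormone receptor and 17 of 27 voltage-gated channel genes. No share of all genes highest in each library was set beside these counts. No member of the mural or astrocyte lists was called over all genes tested.

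Of the tests below, those of nuclear RNA content, of 1 sex in each library, of few sampled molecules (on all genes and on genes used by every cell) and of chance and of untagged RNA for the cholinergic genes were chosen after the result was seen.

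Xist was abundant in replicates 1 and 3, with 886 and 680 counts against 31 in replicate 2, although Y-linked transcripts were present in every library. Nuclear RNA content alone was argued against, since the ratio of Xist to Malat1, a nuclear RNA of both sexes, was at least 10.9 times higher in replicates 1 and 3 than in replicate 2. RNA of 1 sex in each library was also argued against, since the mean of Ddx3y, Eif2s3y, Kdm5d and Uty in replicate 1, the lower of these 2 libraries, was 0.770 times that in replicate 2. RNA from animals of both sexes in replicates 1 and 3 remains open, because the ratio of a Y-linked gene to its X-linked partner lay below that of replicate 2 in 4 of 8 comparisons. The labels give neither the sex of the mice nor any pooling to set these values against, and no other biological explanation was tested.

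Some genes were near all-or-none between the libraries, with 61 genes at 10 CPM or more in 1 library and at 3 or fewer counts in another. Few RNA molecules sampled before amplification may account for this, and the median dispersion at 5 to 10 CPM was 3.16 times that at 50 to 100 CPM. Among genes used by every cell, such as proteasome and complex I subunits, the ratio of 5 to 20 CPM over 50 to 200 CPM was 1.39, with a bootstrap 95% interval of 0.863 to 1.84 from 29 and 77 genes. That interval holds both no rise and the rise this explanation needs, so it remains open, beside real differences between the mice, which were not tested.

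Chat, Slc18a3, Slc5a7, Lhx8 and Isl1, genes of forebrain cholinergic neurons, were each highest in replicate 1, and Slc18a3 had 45 counts there and 0 in the others. Zic1 and Zic4, of the same gene family as Zic5 below, had also been seen before, at 70.5 and 34.9 CPM in replicate 1. They measured 8.34 and 5.06 CPM in replicate 2 and 20.8 and 11.8 CPM in replicate 3. A candidate explanation is that the dissection of replicate 1 held cells of a neighbouring cholinergic area. Of 6 further markers not examined earlier (Slc10a4, Nkx2-1, Ecel1, Prima1, Zic5 and Ache) 6 were highest in replicate 1. These were picked as markers of the same neurons, so they are not independent support for that explanation. Gene-by-gene chance was argued against, with a one-sided exact binomial p of 0.000636 against the 29.3% of genes of like level that are highest there, though co-expressed genes are not independent draws. Markers of other classes were also high there, with 11 of 12 astrocyte, 9 of 12 oligodendrocyte, 9 of 12 GABAergic and 8 of 12 mural genes highest in replicate 1. The same held for 3 of 12 endothelial and 2 of 12 microglial genes. More RNA of untagged cells of every type alike was examined by the rise of 77 non-neuronal markers, which cannot decide it. The 6 markers rose by a median log2 of 1.39 more (bootstrap 95% interval over genes 0.863 to 2.10). That interval covers the choice of genes and not the spread between libraries, since the rise is that of 1 library. However, the 6 were picked from a class already seen to be high in replicate 1. The log2(CPM + 1) scale also understates the rise of low markers. Among the non-neuronal markers, 7 of 12 microglial and 5 of 10 ependymal and choroid genes were not detected. An unequal rise of untagged cell types was not tested. Tagged cholinergic cells, untagged RNA of such cells and an area that brings other cell types along were not separated by any value here, and no biological difference between the mice was tested.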
